A study of Mus musculus with 2 samples.

How the data were processed

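The 2 samples were biological replicates of H3K4me1 chromatin immunoprecipitation from the hindbrain of mouse embryos at 14.5 days, per the labels, from pools of 24 embryos (replicate 1) and 34 embryos (replicate 2) of mixed sex. Both belonged to 1 group, so that results are descriptions, given as mean ± SD over the 2 replicates, and no test between groups was made. The labels call them biological replicates, each from its own pool of embryos.

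The authors deposited 4 peak lists on mm10 in the narrowPeak format. Per the file headers, each replicate's peaks were called by the authors on its filtered alignments with control alignments, from 2 technical replicates for replicate 1 and 1 for replicate 2. The pooled list was called on both replicates together, and the replicated list was derived from the 2 replicate lists and the pooled list, per the file headers. The rule for the replicated list, the peak caller, the aligner, their versions and the thresholds are not given in the sources used here. Column 7 of the deposited lists is a ratio, the fold enrichment of the peak over its control. Columns 8 and 9 of the deposited lists are −log10 of a p-value and of a q-value. Each is the authors' value for one peak and was used here to describe, rank or filter within a list. Read totals were not given, so depth is unknown. A call made at lower depth misses weak peaks, which bears on every count of peaks in one replicate and not in the other. Fragment size, repeats and mappability also shape where a peak can be called.

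Peaks on chromosomes 1 to 19 and X were analysed. Peak and gene coordinates were checked against the sequence lengths of GRCm38, the assembly of mm10, and 0 lay outside. Gene models came from GENCODE release M21 for GRCm38. The start site of a gene was the 5′ end of its gene record, and 21755 protein-coding genes entered. Printed coordinates are 1-based.

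Overlap meant at least 1 bp. Chance overlap came from 20 shuffles within chromosomes with bedtools 2.31.1 and fixed seeds. Genome classes were assigned in the order promoter (1 kb either side of a TSS), exon, intron and intergenic. Promoters were CpG-rich with an observed over expected CpG of at least 0.6 and a GC content of at least 50% within 500 bp of the TSS. Coverage around start sites was read in steps of 100 bp within 5 kb. Gene lists (20 lists of 340 genes, all matched to the annotation, and the olfactory receptor family) were described by the median kb of merged replicated peaks within 50 kb of the TSS. Each median was placed among those of 10000 random lists of the same size, drawn with replacement and matched on the number of other coding TSS within 50 kb (0, 1, 2 to 3, 4 to 6, or more). A list was called above or below when its median lay outside the central 95% of random medians. Shares of marked start sites (peak within 5 kb) have 95% Clopper-Pearson intervals, which cover counting error only.

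For motifs, 22 consensus sequences were searched on both strands in the central 1 kb of distal replicated peaks (midpoint over 1 kb from any TSS). Controls were as many random windows on the same chromosome and in the same 2% bin of GC, touching no pooled peak and over 1 kb from any TSS. A motif was called when the exact 95% intervals of the shares did not overlap. Values were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

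The gene lists, motifs, tests and the first set of alternatives below were fixed before the data were examined, as was the rule for named genes and peaks. It took the 20 protein-coding genes with most replicated kb within 50 kb of the TSS (the first of those with TSS within 100 kb), the 10 replicated peaks with the highest fold and the 5 widest, in each list the 3 members with most kb and the 1 with least, and for each replicate the 5 best-ranked peaks by p-value that touch no peak of the other. Names outside this rule are given as chosen later.

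The functions were tested on simulated data. For gene list coverage over 21755 genes, 5.5% of 200 lists of 20 unchanged genes were called, 73% of lists with a 2-fold gain in one direction, and 100% with a 4-fold gain. These lists held randomly chosen genes with independent values above 0, whereas clustered genes share windows and 21.7% of genes had 0 kb. The rates therefore do not carry over to lists of clustered genes such as Hox genes and olfactory receptors. Motif shares simulated at a ratio of 3 returned 3, and simulated touching and non-touching intervals were told apart in 100% of 20000 cases.

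Alternatives were a stricter threshold (q-value of at most 1e-05), 50% overlap in one direction or both, equal numbers of best peaks, each replicate's list alone, the pooled list, other window and promoter widths, other matching of random lists, 1 gene per 100 kb, motif windows of 400 bp or the whole peak, the 10000 peaks of highest fold and controls shifted by 10 kb. Added after the data were seen were chance overlap by rank of the peak, shuffles outside assembly gaps, strict peaks against the whole other list, lists without X-linked genes, hindbrain against forebrain lists within 5 kb or without Hox genes, controls matched on repeat share, and the X chromosome in each replicate and the pooled list. Peaks on other sequences entered no comparison. Signal tracks, control libraries and reads are not used here.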

Results

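H3K4me1, a histone mark found at enhancers and on the flanks of active promoters, was mapped by chromatin immunoprecipitation and sequencing in the hindbrain of mouse embryos at 14.5 days. At this age the hindbrain holds the brainstem and the early cerebellum. There was 1 group with 2 biological replicates, which were pools of 24 embryos (replicate 1) and 34 embryos (replicate 2) of both sexes. Replicate 1 held 158375 peaks over 61.9 Mb and replicate 2 held 135584 peaks over 51.8 Mb of chromosomes 1 to 19 and X. A pooled list, called by the authors on both replicates together, held 178681 peaks over 90.1 Mb there. From it the authors drew a replicated list of 81638 peaks with a median width of 603 bp, which covered 63.4 Mb or 2.48% of the assembled chromosomes. All lists reached down to weak calls, with a lowest −log10 p of 2.05 (replicate 1), 2.004 (replicate 2), 2.02 (pooled) and 2.03 (replicated) by the authors' values. A q-value of at most 1e-05 was held by 16%, 13%, 31% and 63% of their peaks, in that order. Counts and shares over whole lists below therefore include many weak calls. The files give no read totals, so the depth of each replicate is unknown. The fold enrichment of a peak over its control is the authors' value and served here only to describe or rank peaks within a list. With 1 group of 2 replicates no test between groups was possible, and positions are given on mm10.

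Ncor2, Pipox and Flrt1 had the most peak-covered sequence within 50 kb of their start sites. Ncor2, a nuclear receptor corepressor (chromosome 5, 125017153 to 125179219, minus strand), had 47.9 kb of replicated peaks within 50 kb of its transcription start site (TSS), against a median of 2.81 kb over 21755 protein-coding genes. Its value over the replicates' own lists was 40.3 ± 2.76 kb (SD, n = 2). Pipox, a peroxisomal oxidase gene, followed with 47.8 kb (40.3 ± 6.13 kb) and Flrt1, a neuronal adhesion protein, with 45.5 kb (34.3 ± 10.1 kb). Zmiz1, a transcriptional coactivator on chromosome 14 (25459185 to 25666743, plus strand), had 42.6 kb (35.2 ± 4.80 kb). The 20 leading genes also held Bahcc1 (42.1 kb), Tcf20 (41.9 kb), Cxxc5 (37.3 kb), the Groucho corepressor Tle3 (35.9 kb), the retinoic acid receptor gene Rara (35.8 kb), Cbfa2t3 (35.3 kb), Zfp608 (35.0 kb), Lyl1 (34.7 kb), Ski (34.5 kb), Ahdc1 (34.3 kb), Ssbp3 (33.4 kb) and the circadian repressor Nr1d1 (32.2 kb). The neuronal membrane protein gene Basp1 had 36.0 kb, and Srgap3, a signalling protein of the slit and robo pathway, had 33.5 kb. Ccdc85c (40.5 kb) and the kinase gene Map4k4 (35.4 kb) completed the set. These 20 were ranked on the replicated list, and windows around neighbouring genes can share peaks, as for Lyl1 and Nr1d1, each with 4 other coding TSS inside the window. Pipox and Flrt1 each had 1 other, and Cbfa2t3 had no replicated peak within 5 kb of its TSS.

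Of the 10 replicated peaks with the highest fold enrichment and the 5 widest, all but the first lay inside genes. That first peak, with a fold of 11.6 (11.5 and 9.32 for the peaks it touched in replicates 1 and 2), was intergenic on chromosome 2 (30645435 to 30648627), with Cstad as the nearest coding gene at 52.0 kb. The next, at 10.9, lay inside Fyn, a Src family kinase gene, on chromosome 10 (39540908 to 39544229), and the third, at 10.9, inside Nol4l on chromosome 2 (153482956 to 153484994). Peaks inside Tpp2 (10.4), Fbrsl1 (10.3), Rsrp1 (10.2), Gse1 (10.2), Khdc4 (10.05), Plxnb2 (10.03) and Tsc22d1 (9.99) followed. The 5 widest replicated peaks all lay within genes: Zmiz1 (12681 bp, chromosome 14, 25471734 to 25484414), Ahdc1 (11912 bp), Cxxc5 (10625 bp), Ncor2 (10441 bp) and the kinesin gene Kif21b (10162 bp). Zmiz1, Ahdc1, Cxxc5 and Ncor2 were thus also among the 20 genes with most covered sequence.

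Axon guidance, sonic hedgehog pathway, pan-neuronal and neural progenitor genes carried more H3K4me1 than random genes with as many neighbouring TSS. The 20 axon guidance genes had a median of 8.11 kb of replicated peaks within 50 kb of the TSS (7.47 ± 0.472 kb over the replicates, n = 2), where random lists had 1.71 kb. The receptor gene Ephb2 had 25.6 kb, the semaphorin Sema6a 23.9 kb and the netrin receptor Unc5a 21.6 kb, while Robo1 had 0.246 kb. The 14 genes of the sonic hedgehog pathway, which drives growth of granule cell precursors, had a median of 6.19 kb (5.39 ± 0.857 kb) against 2.12 kb in random lists. The hedgehog receptor gene Ptch1 (22.2 kb) and the coreceptors Boc (20.5 kb) and Cdon (12.4 kb) led this list, and Hhip had the least with 2.08 kb. Pan-neuronal genes had a median of 5.90 kb (6.19 ± 1.0999 kb) against 2.07 kb. Here Rbfox3, which encodes the nuclear antigen NeuN, had 24.3 kb, the adhesion molecule gene Ncam1 16.2 kb, Myt1l 15.2 kb and Elavl4 1.03 kb. Neural progenitor and radial glia genes had a median of 5.48 kb (6.15 ± 2.17 kb) against 1.959 kb, with Notch1 at 30.6 kb, the intermediate filament gene Nes at 20.9 kb, Msi1 at 14.6 kb and the X-linked Sox3 at 0 kb. The percentiles of these 4 medians among 10000 random lists were 100 (axon guidance), 99.8 (sonic hedgehog), 99.9 (pan-neuronal) and 99.9 (neural progenitors). A percentile describes these libraries and is not a p-value across genes.

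Of the lists tied to parts of the hindbrain, those of the isthmus and the ventricular zone lay above the random range, with no test made between lists. The 15 regulators of the isthmus, the signalling centre at the border of midbrain and hindbrain, had a median of 5.72 kb (4.92 ± 1.47 kb) against 2.00 kb in random lists (percentile 99.7). Lmx1b had 16.8 kb, Fgf17 13.3 kb and Gbx2 10.1 kb, while En1 had 1.18 kb. Of these genes Gbx2 alone had a replicated peak within 5 kb of its TSS, as had 10 of the 15 in the list. The window of Fgf17 held 3 other coding TSS. The ventricular zone and Purkinje cell lineage had a median of 3.78 kb (3.60 ± 1.74 kb) against 1.86 kb (percentile 98.3), with Foxp4 at 16.0 kb, Skor1 at 14.1 kb, the vesicular GABA transporter gene Slc32a1 at 11.2 kb and Tfap2b at 0.878 kb. The rhombic lip and granule cell lineage, at 3.66 kb (2.9995 ± 1.0048 kb), stayed just inside the central 95% of random lists (percentile 97.4). In replicate 1's own list it lay just above, at 3.71 kb against an upper bound of 3.70955 kb. Its leading members were Mab21l1 (21.3 kb), Nhlh1 (21.1 kb) and the homeobox gene Meis1 (17.3 kb), and Etv1 had 0 kb. Genes of serotonergic, noradrenergic and motor neurons of the brainstem were also inside the random range, at 2.93 kb (percentile 83.2). Fev had 7.94 kb, the tyrosine hydroxylase gene Th 7.34 kb, Phox2a 6.66 kb and Foxa2 0 kb. The isthmus and ventricular zone lists fell inside the range within 10 kb of the TSS (percentiles 97.45 and 96.3), within 5 kb (70.8 and 73.2), and against random lists matched on gene length (97.4 and 86.4) or unmatched (96.95 and 80.6). The ventricular zone list also did so in replicate 2 alone (89.1) and in the best 50% of peaks by fold (94.0).

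Genes of the hindbrain lists and of the forebrain list differed little once the window was narrowed. The 90 genes of the hindbrain lists (anterior Hox, isthmus, rhombic lip, ventricular zone and brainstem) had a median of 4.46 kb and the 22 forebrain regulators 2.498 kb. The hindbrain lists also hold genes of neuron types, such as Gad1, Th and Chat. They hold Dlx6 too, while Dlx1, Dlx2 and Dlx5 are in the forebrain list. These names were chosen later. The comparison is thus one between lists and does not measure regional identity alone. The difference in medians of 1.959 kb lay on the upper edge of the central 95% of random list pairs, which ran from -1.37 to 1.956 kb. It was above the random range in each replicate's own list too, at 2.30 kb in replicate 1 and 1.99 kb in replicate 2. Within 10 kb of the TSS the difference was 0.308 kb, and without Hox genes it was 1.13 kb, both inside the random range. Among forebrain regulators Eomes had 5.77 kb, Gsx2 4.42 kb, Hesx1 3.45 kb and the X-linked Arx 0 kb, and the list as a whole was at percentile 76.4.

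**Figure D1:**
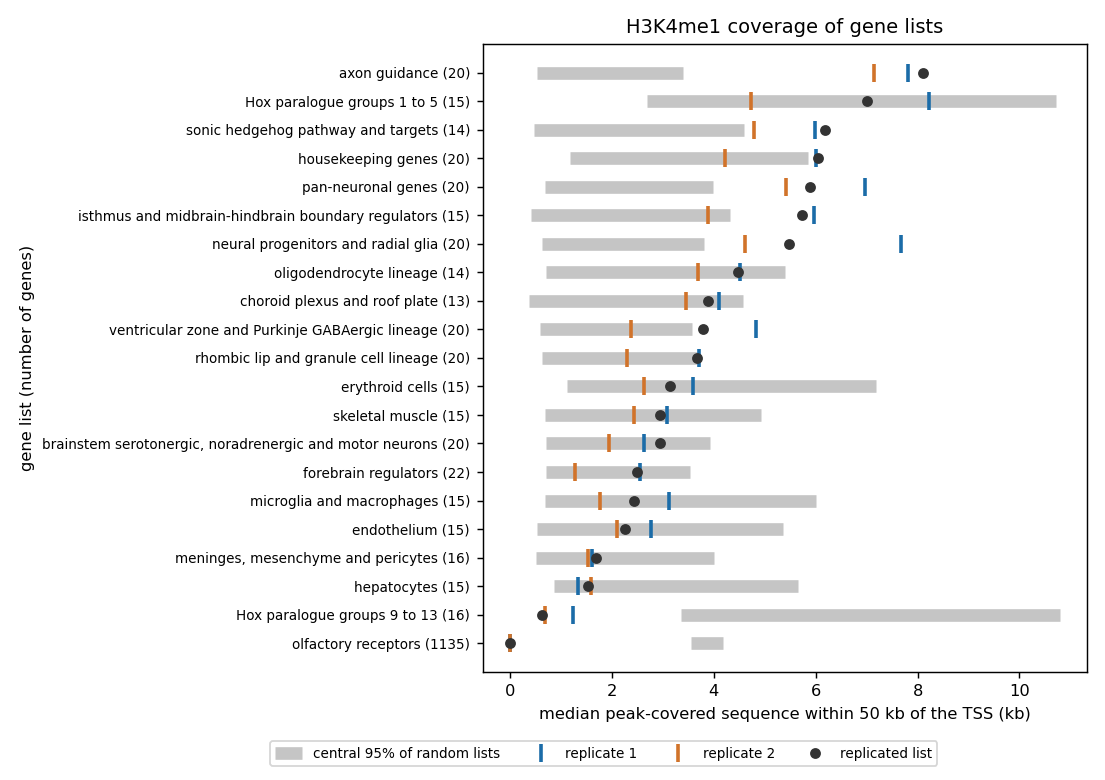
Median peak-covered sequence (kb) within 50 kb of the TSS for each gene list, with the number of genes in parentheses. Dots give the replicated list, coloured ticks each replicate's own list, and grey bars the central 95% of 10000 random lists; axon guidance genes lay highest at 8.11 kb and olfactory receptors lowest at 0 kb.

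Within 50 kb of the TSS, posterior Hox genes, which pattern the trunk and limbs, had little H3K4me1, and the median of anterior Hox genes, which pattern the hindbrain, lay near that of random genes with as many neighbours. The 16 genes of paralogue groups 9 to 13 had a median of 0.634 kb (0.961 ± 0.388 kb over the replicates), against 7.32 kb in random lists (percentile 0.13). The 15 genes of groups 1 to 5 had 7.004 kb (6.48 ± 2.47 kb) against 6.94 kb (percentile 52.4). Anterior members with most kb were Hoxb1 (11.002 kb), Hoxa1 (9.68 kb) and Hoxa2 (9.68 kb), and Hoxc5 had 0.850 kb. The gene record of Hoxc5 starts at 102967443 on chromosome 15, close to that of the posterior Hoxc10 at 102966796, which also had 0.850 kb. Records of Hoxd3 (74711927) and Hoxd4 (74711929) on chromosome 2 start almost together. The 5′ end of Hoxa3 (52213336, chromosome 6) lies next to Hoxa7. Windows of these anterior genes may thus not be centred on their own promoters, which bears on every count for this list. Hoxd9 (5.73 kb), Hoxd10 (4.97 kb) and Hoxd11 (3.97 kb) led the posterior genes, and Hoxa10 had 0 kb, although the replicates' own lists gave it 1.09 ± 0.102 kb. These windows overlap within a cluster: with 1 gene per 100 kb kept, the posterior list had 4 genes with a median of 1.86 kb, against 7.79 kb in random lists and inside their range (percentile 4.14). With random lists matched on gene length the anterior list was above the range at percentile 99.6, and the posterior list at 12.8, where the range began at 0 kb and no value could lie below it. Within 10 kb of the TSS both lists had a median of 0 kb. The posterior list was below its random range there (0.289 to 2.84 kb), and the anterior list could not be, since its own range began at 0 kb (percentile 1.36, random median 1.51 kb). Within 5 kb both random ranges began at 0 kb, and both medians were 0 kb, against 1.02 kb (posterior) and 0.996 kb (anterior) in random lists. In that window, 6 of the 15 anterior genes had replicated peaks: Hoxb2 (4.46 kb, 2.91 ± 0.503 kb over the replicates), Hoxd1 (1.58 kb), Hoxa1 (1.44 kb), Hoxc4, Hoxa2 and Hoxa4. So did 5 of the 16 posterior genes, Hoxd9 to Hoxd13, with 0.276 to 0.658 kb. The genes with peaks within 5 kb are named by that count, after their values were seen. Cluster totals, chosen likewise, were 8.31 kb in Hoxb (chromosome 11, 96194316 to 96368256), 6.89 kb in Hoxa, 8.52 kb in Hoxd and 1.27 kb in Hoxc (chromosome 15, 102921103 to 103036852).

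**Figure D2:**
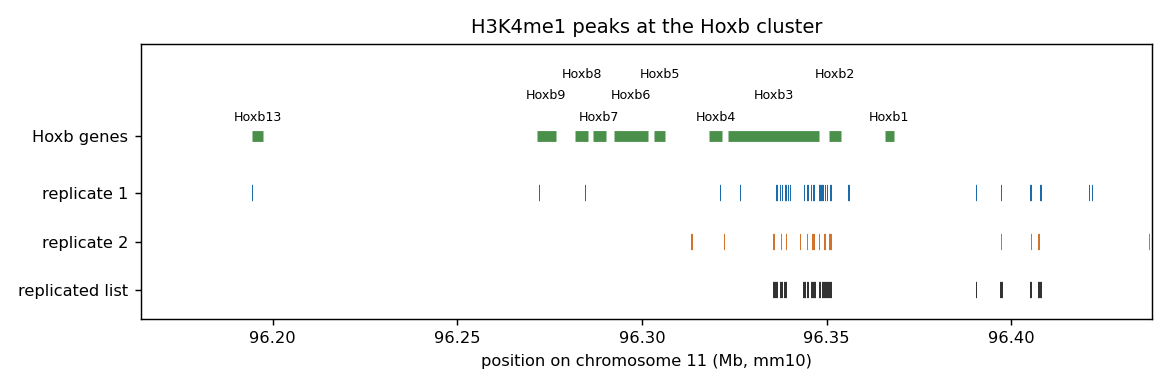
Map of the Hoxb cluster on chromosome 11 (x axis, position in Mb, mm10) with Hoxb genes in green and peaks of replicate 1, replicate 2 and the replicated list as bars on separate tracks. Replicated peaks inside the cluster summed to 8.31 kb and lay at Hoxb3 and Hoxb2, and of the Hoxb genes drawn Hoxb2 alone had a replicated peak within 5 kb of its TSS.

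Markers of other cell types that dissected hindbrain could hold stayed inside the random range. Oligodendrocyte lineage genes had a median of 4.48 kb (percentile 91.1), led by Sox8 (12.8 kb), Cspg4 (9.89 kb) and Cnp (9.28 kb), with the X-linked Plp1 at 0 kb. Choroid plexus and roof plate genes had 3.89 kb (percentile 93.6), led by Msx2 (8.44 kb), Bmp7 (8.01 kb) and Foxj1 (6.55 kb), with Ttr at 1.00 kb. Endothelial genes had 2.26 kb (percentile 41.6; Sox18 8.92 kb, Egfl7 8.82 kb, Esam 7.89 kb, Tek 0 kb). Genes of meninges, mesenchyme and pericytes had 1.69 kb (percentile 36.7), with Pdgfrb at 7.56 kb, Prrx1 at 4.07 kb, Foxc2 at 3.93 kb and Col3a1 at 0 kb. Erythroid genes had 3.15 kb (percentile 30.0) and microglia and macrophage genes 2.43 kb (percentile 33.2). Single members stood high in both: Nfe2 had 20.0 kb, Klf1 9.77 kb, Slc4a1 9.73 kb and the neighbouring complement genes C1qb, C1qa and C1qc had 11.2, 10.8 and 10.2 kb, whereas Gata1 and Adgre1 had 0 kb.

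Genes of muscle, liver and olfactory neurons served as lists from other tissues. Skeletal muscle genes had a median of 2.94 kb (percentile 65.4), with Des at 16.5 kb, Tnnt3 at 9.74 kb, Tnni1 at 9.17 kb and Myf5 at 0 kb. Hepatocyte genes had 1.53 kb (percentile 9.24), with Foxa3 at 7.54 kb, Tat at 3.42 kb, Hnf1a at 3.16 kb and Ambp at 0 kb. Of 1135 olfactory receptor genes, 1010 had no replicated peak within 50 kb, and their median of 0 kb lay below the random range. Housekeeping genes had a median of 6.05 kb (5.11 ± 1.27 kb) against 3.29 kb in random lists (percentile 98.2), led by Vcp (14.3 kb), Hmbs (11.2 kb) and Polr2a (10.9 kb), with the X-linked Hprt at 0.861 kb. In replicate 2 alone the housekeeping list was at percentile 97.02, inside the range.

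Within 5 kb of the TSS, every listed housekeeping and hedgehog gene was marked and almost no olfactory receptor. A replicated peak lay within 5 kb of the TSS of all 20 housekeeping genes (95% Clopper-Pearson interval 83.2% to 100%) and of all 14 sonic hedgehog genes (76.8% to 100%). The share was 90% for neural progenitor, pan-neuronal and axon guidance genes alike (68.3% to 98.8%, 18 of 20 each) and 61.9% over all coding genes (61.3% to 62.6%). It was 40% for anterior Hox genes (16.3% to 67.7%), 31.3% for posterior Hox genes (11.02% to 58.7%), 26.7% for hepatocyte genes and for microglia genes (7.79% to 55.1% each), and 0.441% for olfactory receptors (5 of 1135, 0.143% to 1.03%). The other lists ranged from 33.3% for erythroid to 85% for ventricular zone genes. Intervals here and below cover counting error only. Over all autosomal coding genes the share was 94.1% at CpG-rich and 38.1% at CpG-poor promoters. The lists were not split by that class, so promoter type and cell type cannot be told apart in their shares. The replicates differed most for posterior Hox genes, of which 62.5% were marked in replicate 1 and 18.8% in replicate 2, and for anterior Hox and muscle genes (86.7% against 53.3%, and 80% against 46.7%).

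At CpG-rich promoters H3K4me1 flanked the start site and was depleted on it. Of 9737 such promoters, 6.17% were covered by a replicated peak at the TSS itself, 32.0% at 800 bp upstream and 55.0% at 1100 bp downstream. The downstream maximum was 8.92 times the value at the TSS, with 8.08 in replicate 1 and 11.3 in replicate 2. The 12018 CpG-poor promoters had no such dip: 8.92% were covered at the TSS, 9.80% at 300 bp upstream and 12.2% at 700 bp downstream.

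**Figure D3:**
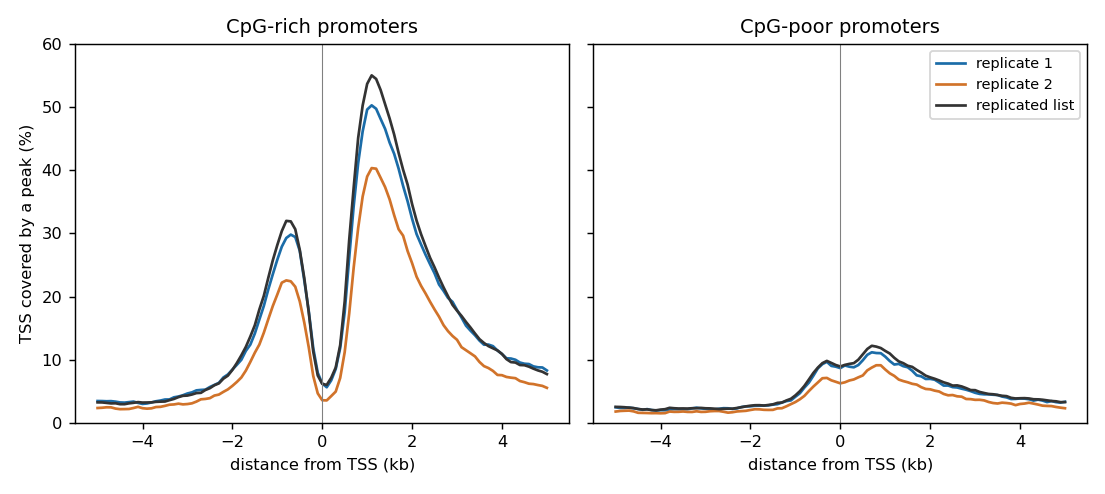
Percent of protein-coding TSS covered by a peak (y axis) against distance from the TSS (x axis, kb, positive downstream) for CpG-rich and CpG-poor promoters, one line per peak list. At CpG-rich promoters coverage in the replicated list ran from 6.17% at the TSS to 55.0% downstream.

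Most of the marked sequence was intronic. Introns held 59.9% of replicated peak bases, 1.46 times their share of the genome. Promoters (1 kb either side of any TSS) held 13.7%, a 3.53-fold excess, with 12.6 ± 0.942% over the replicates (3.25 ± 0.243-fold, n = 2). Exons held 6.55% (1.66-fold), and intergenic sequence held 19.9%, which was 0.389 of its share of the genome. With promoters drawn around protein-coding genes alone the excess was 6.17-fold.

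Binding sequences of RFX, NFI, POU and homeodomain factors were more frequent in distal peaks than in windows of the same GC content. Distal peaks had midpoints over 1 kb from any TSS. They can include flanks of CpG-rich promoters, where coverage was highest at 1100 bp downstream, and are not enhancers alone. The full X-box, the palindromic site of RFX factors such as Rfx4 of the neural tube, was present in 0.412% of 69585 distal peak windows (95% exact interval 0.366% to 0.463%) and 0.0244% of control windows (0.0142% to 0.0391%), a ratio of 16.9. The replicates' own lists gave 11.6 ± 1.05 (SD, n = 2). Its single arm had a ratio of 2.20 (1.93 ± 0.0548). The palindrome of NFI, a family of glial and neuronal regulators, had a ratio of 2.25 (2.79 ± 0.483). The homeobox core TAATTA stood in 29.4% of peak windows and 19.5% of controls, a ratio of 1.503 (1.45 ± 0.0156). MEF2 (1.64), ZIC (1.45), POU octamer (1.32), the E-box CAGCTG (1.21) and MEIS (1.15) were also above the control, as were HOX-PBX (1.38) and TEAD (1.101). The proneural E-box CAGATG (1.01) and GLI (0.942) had intervals that overlapped those of the controls. Among motifs of other tissues or promoters, chosen for comparison, so had ETS (1.08), GATA (1.03), NRF1 (1.19), HNF4 (0.981) and HNF1 (1.66). Other comparison motifs were called, so a call does not by itself mark a factor of the hindbrain. In the replicates' own lists HNF1 was above the control (1.797 in replicate 1 and 1.87 in replicate 2), and in that of replicate 1 NRF1 was above (1.47) and GLI below (0.871). In the best 10000 peaks by fold NFI (4.67), HOX-PBX (1.31) and TEAD (1.05) no longer had intervals apart from the controls, nor had HOX-PBX in windows shifted by 10 kb (1.13). CTCF had a ratio of 1.48 in windows of 1 kb and 0.696 over whole peaks, and REST one of 4.60, from sites in 0.0331% of windows, a call lost over whole peaks (2.43), in shifted windows (1.88), in the central 400 bp (1.17), with repeats matched (2.88) and in the best 10000 peaks (1.00). AP-1 was below the control at 0.964, but not in replicate 1's own list (1.00) and above it in that of replicate 2 (1.04). SOX was below the control at 0.927, but peak windows held 14.7% soft-masked repeat sequence and controls 31.3%, and with controls also matched on that share SOX was above at 1.15 and TEAD at 1.01 no longer differed. The matching on repeats was chosen after these values were seen.

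The X chromosome had far fewer peaks than any autosome. It held 3.27 replicated peaks per Mb, against 33.9 over the autosomes, a ratio of 0.0967 (0.125 in replicate 1 and 0.107 in replicate 2). Against autosomal 100 kb windows matched on coding TSS and repeat share the ratio was 0.227 (3.52 and 15.5 replicated peaks per Mb). At a q-value of at most 1e-05 the replicates' ratios were 0.0456 and 0.0320. The lowest autosome, chromosome 14, had 25.6 and the highest, chromosome 11, had 51.9 peaks per Mb. Of 948 X-linked coding genes, 61.8% had no replicated peak within 50 kb of the TSS, against 19.8% of autosomal genes. Among X-linked genes, which were picked after the density was seen, the corepressor gene Bcor had 8.30 kb, Dcx, a microtubule protein of migrating neurons, 7.99 kb, and the plexin gene Plxna3 6.93 kb. At CpG-rich promoters, a peak lay within 5 kb for 54.0% of 226 X-linked TSS (47.2% to 60.6%) and 94.1% of 9511 autosomal TSS (93.6% to 94.6%). Sox3, Plp1 and Hprt, all X-linked, had the least kb in their lists, and X-linked Arx, Gata1 and Zic3 were at 0 kb together with autosomal members of theirs (Nkx2-1; Hbb-bt and Hbb-bs; Etv1), ties that were looked up after their values were seen.

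**Figure D4:**
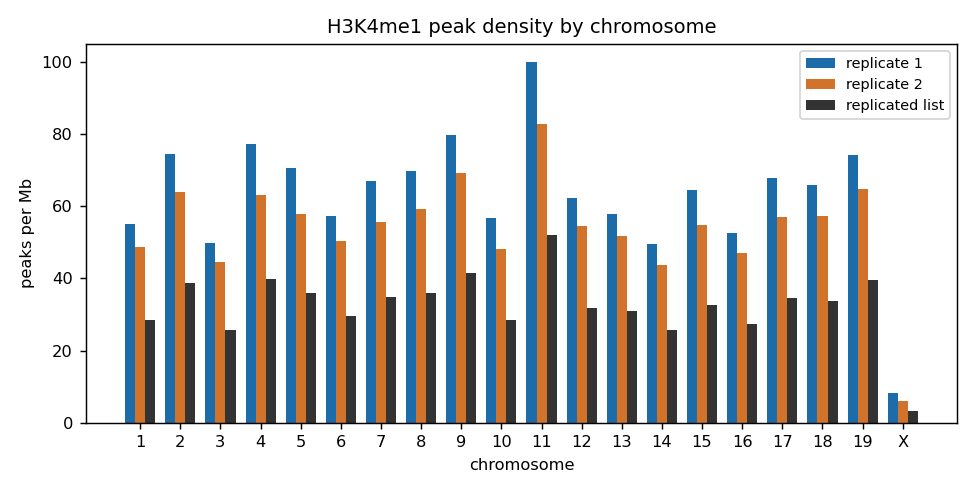
Peaks per Mb (y axis) on each chromosome (x axis) in replicate 1, replicate 2 and the replicated list. Chromosome X, at 3.27 replicated peaks per Mb, stands below every autosome, the lowest of which had 25.6.

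The strongest peaks of each replicate touched the other's whole list more often than its weakest ones did. Of replicate 1 peaks 49.7% touched a peak of replicate 2 by at least 1 bp, and 58.8% of replicate 2 peaks touched one of replicate 1. Peaks shuffled within chromosomes gave 4.23 ± 0.0572% and 4.90 ± 0.0638% (SD over 20 shuffles). In the 10% of peaks with the best p-values, 91.9% of replicate 1 and 94.6% of replicate 2 touched the other list, and in the weakest 10% these shares were 31.2% and 40.7%. The strongest were also wider (medians of 786 and 660 bp, against 203 and 227 bp). Against shuffled peaks they touched in 7.19 ± 0.217% and 7.42 ± 0.214%, and the weakest in 3.42 ± 0.154% and 4.13 ± 0.189%. With both lists held to a q-value of at most 1e-05, 38.1% of replicate 1 and 58.8% of replicate 2 peaks touched the other, and with the same number of best peaks 51.2% and 53.8%. The Jaccard index of covered bases was 0.309, or 26.2 times the shuffled mean, and 0.264 at that q-value. When 50% reciprocal overlap was required, 22.7% and 26.5% of peaks were shared. Across 63804 replicated peaks the rank correlation of fold enrichment between the replicates was 0.315 (Spearman's rho across peaks, which are not independent replicates).

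**Figure D5:**
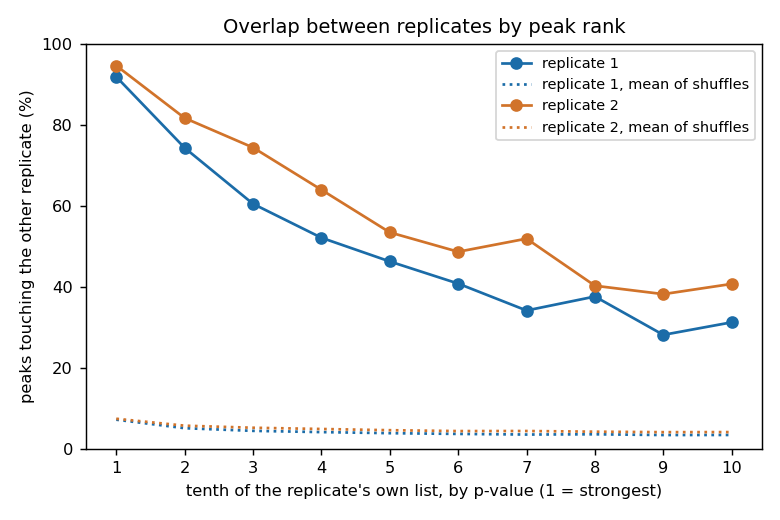
Percent of each replicate's peaks that touch a peak of the other (y axis) by rank of the p-value in the replicate's own list (x axis, strongest at 1, weakest at 10). Solid lines are the observed shares, 91.9% and 94.6% at rank 1 and 31.2% and 40.7% at rank 10, and dotted lines the means of 20 shuffles for the same peaks, 7.19% and 7.42% at rank 1 and 3.42% and 4.13% at rank 10.

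Regions found in a single replicate had lower fold enrichment than shared ones. In replicate 1, 79644 peaks (median fold 3.203, against 3.78 for shared peaks) did not touch replicate 2, of which 3658 had a q-value of at most 1e-05. Its 5 best-ranked such peaks lay inside or beside Ap5b1 (chromosome 19, 5568419 to 5568948), Dalrd3, Ccdc151 and Fcf1, each within 1 kb of a coding TSS, and 36.8 kb from the TSS of Cryba4. In replicate 2, 55860 peaks (2.99 against 3.38) did not touch replicate 1, of which 1210 had such a q-value. Its 5 best-ranked lay in Zfp105 and Cdkl3, 36.9 kb from Zfp281, 210 kb from the olfactory receptor gene Olfr1505 and 396 kb from Gm6657. Of peaks in replicate 1 alone, 4.38% lay within 1 kb of a CpG-rich TSS (4.24% to 4.52%), and of peaks in replicate 2 alone 2.45% (2.32% to 2.58%).

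The replicated list kept 45.7% of the pooled peaks and 70.3% of their covered bases. Replicate 1 touched 91.7% of its peaks and replicate 2 touched 85.8%. Of 65131 pooled peaks that touched both replicates' lists, 63804 were kept, and 17834 kept peaks did not touch both. A further 30846 pooled peaks touched neither replicate's list, and 537 of these were kept. Kept peaks had a median width of 603 bp and left-out peaks 244 bp.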

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

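Sequences outside chromosomes 1 to 19 and X, which entered no comparison, held 5 peaks in replicate 1 and 4 in the pooled list, more than the 3 that a count of 0 allows. Of the 5 in replicate 1, 1 lay on chromosome Y (90719663 to 90719837, fold 3.84) and 4 on an unplaced sequence assigned to the X. All 4 in the pooled list lay on that unplaced sequence, with folds from 2.85 to 4.02. Replicate 2 and the replicated list held 1 such peak each. No explanation was tested for these counts.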

How the results depend on the processing

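Chosen after the data were seen were the settings without Hox genes, without X-linked genes, within 5 kb for hindbrain against forebrain lists, with controls matched on repeats, with shuffles outside assembly gaps, with strict peaks against the whole other list, and for the X ratio the pooled list and each replicate alone. Of 581 alternative values, 434 stayed on the same side or within the spread set for the result, and 91 moved by more. A call was lost by 34 and gained by 15. Another 7 changed their call and crossed to the other direction, some of them only to a value inside the range. The cause was not tested unless stated. That spread was the SD over the 2 replicates for most results. For shared peaks it was the SD of the 2 directions of overlap, and for the Jaccard ratio that of shuffles. None was set for the Jaccard index, rho and the share of pooled peaks kept, so any change counted as moved. Numbers of called lists or motifs were held to a fold limit. With 50% of the peak covered, the mean share of replicate peaks that were shared was 40.5%, in the best 10% it was 80.7% and in the weakest 10% 25.1%, and a replicate covered 72.1% of replicated peaks. Reciprocal overlap gave 24.6% shared peaks, strict peaks in both lists 48.4%, the same number of best peaks 52.5%, strict peaks against the whole other list 89.3%, and shuffles outside gaps a Jaccard ratio of 25.4. Rho was 0.415 with p-values ranked and 0.332 in distal peaks. At a q-value of at most 1e-05, 93.0% of pooled peaks were in the replicated list, the X ratio was 0.0717 (0.0456 and 0.0320 in the lists of replicates 1 and 2) and the intergenic fold 0.356. In the pooled list promoter and intergenic folds were 3.15 and 0.430, the X ratio 0.124, and marked TSS 68.8%. The promoter fold was 2.91 within 500 bp and 6.17 around coding genes. Marked TSS within 1 kb were 50.7%, a narrower window by construction. Among gene lists, 242 of 264 alternative values kept their call, 15 lost it and 7 gained one. These values were percentiles and, for each setting, the number of lists above the random range, which stayed within its limit throughout. Posterior Hox genes were at percentile 4.14 with 1 gene per 100 kb, which left 4 genes (1.86 kb, random 7.79 kb). They were at 2.33 within 5 kb (0 kb, random 1.02 kb), 1.315 over gene bodies (0% covered, random 7.68%) and 12.8 against length-matched lists (0.634 kb, random 2.43 kb), where the random range began at 0 and allowed no call below it. Anterior Hox genes were at 99.4 against unmatched and 99.6 against length-matched lists. Isthmus genes were at 97.45 within 10 kb, 70.8 within 5 kb, 96.95 unmatched and 97.4 length-matched. Ventricular zone genes were at 96.3 within 10 kb, 73.2 within 5 kb, 94.0 in the best 50% of peaks by fold, 80.6 unmatched and 86.4 length-matched. Rhombic lip genes gained a call at 98.7 over gene bodies, 99.4 in the pooled list, 97.6 without X-linked genes and, at 3.71 kb against an upper bound of 3.70955 kb, without replicate 2, and forebrain regulators at 99.8 over gene bodies. The hindbrain minus forebrain difference was 0.308 kb within 10 kb, 1.13 kb without Hox genes and, with the opposite sign, -0.06 kb within 5 kb, all inside the random range. Of the 21 lists, 18 had a higher share of marked TSS in the pooled list, and 19 a lower share within 1 kb. SOX was at 1.04 (central 400 bp), 1.01 (whole peak), 0.983 (shifted windows), 1.15 (repeats matched) and 0.877 (best 10000 peaks). AP-1 was at 0.950344, 0.996 and 0.960 in the central 400 bp, the whole peak and the best 10000 peaks, where it lost its call, and stayed below at 0.924 in shifted windows and 0.878 with repeats matched. The E-box CAGATG was above the control in the central 400 bp (1.05), the whole peak (1.02) and shifted windows (1.03), and HNF4 below it with repeats matched (0.873). CTCF was at 1.07, 0.696 and 1.00, and REST at 1.17, 2.43 and 1.00, in the central 400 bp, the whole peak and the best 10000 peaks, with REST at 1.88 in shifted windows and 2.88 with repeats matched, and its call lost in all 5 of these settings. In the best 10000 peaks NFI was at 4.67, HOX-PBX at 1.31 and TEAD at 1.05, and 8 motifs stayed above the control. HOX-PBX was at 1.13 in shifted windows and TEAD at 1.01 with repeats matched. With each replicate left out in turn, ranges were 64.1% to 66.6% for marked TSS, 8.08 to 11.3 for the CpG-rich promoter ratio, 0.107 to 0.125 for the X ratio at the authors' threshold, 3.08 to 3.42 for the promoter fold and 0.393 to 0.435 for the intergenic fold. Percentiles ran from 97.02 to 98.7 (housekeeping), 84 to 98 (rhombic lip, rounded to whole numbers) and 89.1 to 99.8 (ventricular zone), and AP-1 ran from 1.00 (replicate 1's list, intervals overlapping) to 1.04 (replicate 2's list, above the control). Depth, unknown here, limits weak peaks and all shares of peaks found in a single replicate.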

Other observations

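Among the tests of explanations given here, that of read depth on the X chromosome was chosen after the result was seen; the peaks with an X-box, the X-linked genes and the flanks of Hox clusters were also picked then. The full X-box stood in 287 of 69642 distal replicated peaks. These had a median fold of 4.19, against 3.57 for all distal peaks, and 71 of them (24.7%) were in the best 10% by fold. The highest fold, 8.70, belonged to a peak inside Lasp1, an actin-binding protein gene, with GTTGCCATGGGAAC on chromosome 11 at 97812813 to 97812826. A peak inside Nav1, a neuron navigator gene, held GTTGCCATGGAAAC on chromosome 1 at 135581212 to 135581225 (fold 8.33). The fully palindromic GTTGCCATGGCAAC stood inside Mbd6 on chromosome 10 at 127286838 to 127286851 (8.18), inside the potassium channel gene Kcnh2 on chromosome 5 at 24344202 to 24344215 (7.62), and 30.9 kb from Adcyap1r1 (7.58), a neuropeptide receptor gene on chromosome 6. Tcf20, among the 20 genes with most covered sequence, and the synapse gene Nrxn3 also held such peaks (7.35 and 7.20).

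The Hoxc cluster had less H3K4me1 inside it than the other Hox clusters had, and more beside it. Replicated peaks covered 1.27 kb of its 116 kb (1.01 kb in replicate 1 and 1.14 kb in replicate 2), but 18.0 and 29.5 kb of the 200 kb on either side. The like flanks held 8.12 and 13.045 kb around Hoxb (8.31 kb in 174 kb), 6.99 and 3.24 kb around Hoxa (6.89 kb in 105 kb) and 3.22 and 2.93 kb around Hoxd (8.52 kb in 96.8 kb). Flanks were not matched on the number of coding TSS. The flank after Hoxc overlaps the 50 kb window of Nfe2, which had 20.0 kb and 3 other coding TSS. At CpG-poor promoters of the X chromosome a peak lay within 5 kb for 13.3% of 722 TSS (10.9% to 16.0%), against 38.1% of 11296 autosomal ones. Bcor, first among X-linked genes, had 8.23 ± 1.48 kb over the replicates (n = 2), and Dcx 6.91 ± 0.605 kb. Next to Plxna3, Lage3 (6.78 kb) and Gdi1 (6.35 kb) had windows that overlapped its own.

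The X chromosome held 0.0967 times the autosomal number of replicated peaks per Mb. Few genes and many repeats are excluded as the whole cause. Against autosomal 100 kb windows matched on coding TSS and repeat share, the X still had 3.52 peaks per Mb to their 15.5, a ratio of 0.227. Its 95% interval, 0.193 to 0.263, came from resampling the X windows as if independent, with autosomal values held fixed. It does not cover variation between replicates. Lower read depth from fewer X copies in males may contribute. Whether it is the whole cause is not settled. The list of a single replicate kept at least 0.306 of the autosomal density of the pooled list, where the X held 0.0731 of it at the same q-value. A single replicate has fewer reads on every chromosome, whereas fewer copies lower the X alone, so this comparison cannot decide. Gene and repeat content and depth acting jointly, the X content of the control and biological explanations were not tested.

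Peaks in replicate 1 alone lay near CpG-rich TSS more often than those in replicate 2 alone (4.38% against 2.45%). The longer list of replicate 1 is excluded as the whole cause: with the same number of best peaks from each, the shares were 4.69% and 2.63%, a ratio of 1.79. A GC bias between the libraries may account for it and stays open. GC in distal peaks of replicate 1 alone was higher by 0.977 percentage points (0.907 to 1.05). That interval includes the 1 point set beforehand as its mark, and it treats peaks as independent, with 1 replicate on each side. Peaks over 1 kb from any TSS can still flank CpG-rich promoters, where coverage was highest at 1100 bp downstream. The GC comparison is thus not independent of the pattern and cannot decide. No biological explanation was tested, as both replicates belong to 1 group.

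Of the replicated peaks, 17297 touched the list of 1 replicate alone. Small gaps between called intervals are excluded as the whole cause, because 40.7% (40.0% to 41.4%) lay within 500 bp of a peak of the other replicate, against 34.5% of pooled peaks that touched 1 list and were left out. Selection on strength in the pooled list may play a part and stays open. A kept peak had the smaller pooled p-value in 79.5% of pairs with a left-out peak, with median −log10 p of 6.53 and 4.73. No biological explanation was tested.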
